A study of Homo sapiens with 8 samples.

How the data were processed

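Human bronchial epithelial cells were incubated with 4-thiouridine, a uridine analogue that marks newly made RNA, for 10 min, per the labels' protocols. Ribosomal RNA was depleted and stranded libraries were made. The labels list 8 samples, 4 of labelled (nascent) RNA and 4 of total input RNA. The 4 input samples were not analysed here. The nascent libraries are called A1, A2, F1 and F2, after the letter and number of their labels, and are replicates 1 to 4 of 1 group in that order. The labels do not say what the letter or the number stands for, or whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

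The authors deposited 1 list of splice junctions per nascent library. Per the file headers, each junction has its position, strand, a motif code, a flag for annotated junctions, the count of uniquely mapped reads, the count of multiply mapped reads, the longest overhang in bases and a class of splice site. The deposited counts are whole numbers of reads. The submitters' processing notes name Trimmomatic, STAR and the build hg19, without versions. The annotation and the procedure behind the 11 classes are not given in the sources used here. Each listed junction had at least 2 unique reads, so a junction missing from a library may have had 0 or 1 there, and no upper limits for missing junctions are given. The deposited class totals matched the lists for every library and class. A second deposited workbook held the same values in 5 of 5 sheets and was not used.

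The other values derived from the deposited columns are described next. The motif code was read as in STAR's junction tables, where 1 and 2 are GT/AG introns on either strand. What the classes hold was tested on the lists. Of the junctions called intron_5_prime_match (5′ matches below), 96.0% shared their 5′ end with a known-intron junction in these lists and 0% shared the 3′ end. Of those called intron_3_prime_match (3′ matches), 94.3% shared the 3′ end and 0% the 5′ end. Of those called multiple_matches, 94.2% had both ends in use by known introns. The classes called no_match, exonic and not_found shared neither end, and 64.5% of intronic junctions shared neither. Below, junctions called no_match are described as having no known end, meaning none in use by known introns in these lists.

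The lists give positions and no gene names, and the annotation at hand was of another build, so no gene is named and positions are printed as in the lists (hg19, counted from 1). The comparison of letters was planned per gene, or per junction if no gene could be named, and was therefore run per junction. The gene-list test, and the comparison of host genes with random lists, both planned, need gene names and were not run. The planned search for AG followed by GT at junction ends needs the genome sequence of hg19 and was not run, and the shares of motif codes stand in its place. For results that need a unit larger than a junction, known-intron junctions on 1 strand at most 500 bases apart were joined into 18132 clusters, with a median of 5 known-intron junctions each. A junction of another class joined the cluster that holds both of its ends. Clusters held 88.1% of the 215744 junctions and 99.0% of unique reads. This unit was chosen after seeing the data, as were links of 250 and 2000 bases, which gave 22416 and 15464 clusters. A cluster is not a gene: neighbouring genes on 1 strand can share a cluster, and a gene with a long exon can be split.

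Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment at 0.05 and 2 libraries per letter. DESeq2 1.42.0 was an alternative. The balance of other classes against known introns per cluster was tested as the interaction of letter and kind of junction in 8 columns, with the library as a term and TMM factors for each kind, over clusters with at least 20 reads of other classes. Class shares were compared between letters by an exact permutation test, two-sided, whose smallest possible p with 2 against 2 is 0.333. Spans were compared with known introns by an exact sign-flip test over 4 libraries, two-sided, whose smallest possible p is 0.125. Intervals for shares are exact binomial, at 95%, and cover counting error only, since reads carry no molecular identifiers. Sharing between libraries was set against the share expected from known introns with the same total reads. Thinning drew each library down to the 3785119 unique junction reads of F2 with a fixed seed and again dropped junctions under 2 reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

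The rule for naming was fixed before the data were examined. For the letters it takes up to 10 items in each direction with adjusted p under 0.05, a mean of at least 50 reads per library and no overlap of scaled counts (CPM) between letters. It also takes the 15 hosts with the most junctions of each other class at 3 or more reads in every library, and the 5 junctions with the most reads per class. Its parts on gene lists were not used. Because items have no gene names, at most 2 junctions per direction are printed, and hosts and top junctions are given by a few examples. Chromosomes X and Y were left out of named items, and chromosome 6 was left out of named hosts, a choice made after seeing the data. Alternatives covered normalization, count filters, tools, minimum reads, weights, thinning, the title number as a block and each library left out in turn.

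The letter test was tested on simulated data with 200 changed junctions among 91216, where each changed junction had at least 200 reads over the 4 libraries. It called 64% of 4-fold changes and 2% of 2-fold changes at these library sizes, and 0 of the 66 junctions it called were unchanged ones. Simulated junctions varied independently, which junctions of 1 cluster need not do. The 0 therefore does not measure false calls in the real comparison. The match on reads was tested on 4653 simulated junctions with the same detection as known introns, where the observed share differed from the matched one by -0.52 percentage points. Between libraries, chi-square per degree of freedom over junctions with at least 100 reads in total ranged from 4.36 (A2 and F2) to 9.82 (A2 and F1), so no pair was as close as 2 counts of 1 library would be. This does not show whether the libraries are separate biological replicates.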

Results

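Splice junctions were listed for 4 libraries of newly made RNA from human bronchial epithelial cells, which line the airways. The study asked how introns are removed from nascent RNA and how often removal proceeds in pieces, termed recursive splicing. The libraries A1, A2, F1 and F2 held 158314, 155549, 167251 and 132697 junctions. Their unique junction reads numbered 8496823, 8092538, 10979796 and 3785119, so F2 was the shallowest. Over the 4 libraries 215744 different junctions were listed.

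Known introns made up most of the junctions and junction reads listed for the nascent libraries. How much RNA made before the labelling these libraries held was not tested. They accounted for 80.3% ± 3.92 (SD, n = 4) of listed junctions and 97.6% ± 0.0409 (SD, n = 4) of unique junction reads. Junctions of the other 10 classes made up 19.7% ± 3.92 (SD, n = 4) of junctions and 2.35% ± 0.0409 (SD, n = 4) of reads. The largest of these by junctions were 5′ matches, which keep a known 5′ splice site and end elsewhere, at 5.08% ± 1.25 (SD, n = 4). They were followed by 3′ matches, which keep a known 3′ splice site, at 4.49% ± 1.02 (SD, n = 4). Junctions called no_match, with no end in use by a known intron of the lists (no known end below), held 4.11% ± 0.519 (SD, n = 4). Junctions called multiple_matches (multiple-match junctions), 94.2% of which had both ends in use by known introns, held 3.18% ± 0.819 (SD, n = 4). Whether an exon lay between these ends was not tested. Intronic junctions held 1.99% ± 0.27 (SD, n = 4) and exonic ones 0.468% ± 0.0834 (SD, n = 4). By reads, 5′ matches, 3′ matches and junctions with no known end held 0.548% ± 0.0405, 0.50% ± 0.0332 and 0.482% ± 0.0407 (SD, n = 4). With multiply mapped reads included, the order turned: junctions with no known end held 1.06% ± 0.0199, 3′ matches 0.614% ± 0.059 and 5′ matches 0.589% ± 0.0403 (SD, n = 4).

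The share of junctions outside known introns followed depth, while their share of reads hardly moved. It was 21.3% in A1 (exact binomial interval 21.1 to 21.5%), 20.4% in A2, 23.0% in F1 and 14.01% in F2. With every library thinned to the reads of F2, the values were 12.4%, 12.1%, 11.4% and 14.01%. Requiring 10 reads per junction left 3.23% ± 1.06 (SD, n = 4) of junctions outside known introns, so most of them rested on a few reads.

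**Figure D1:**
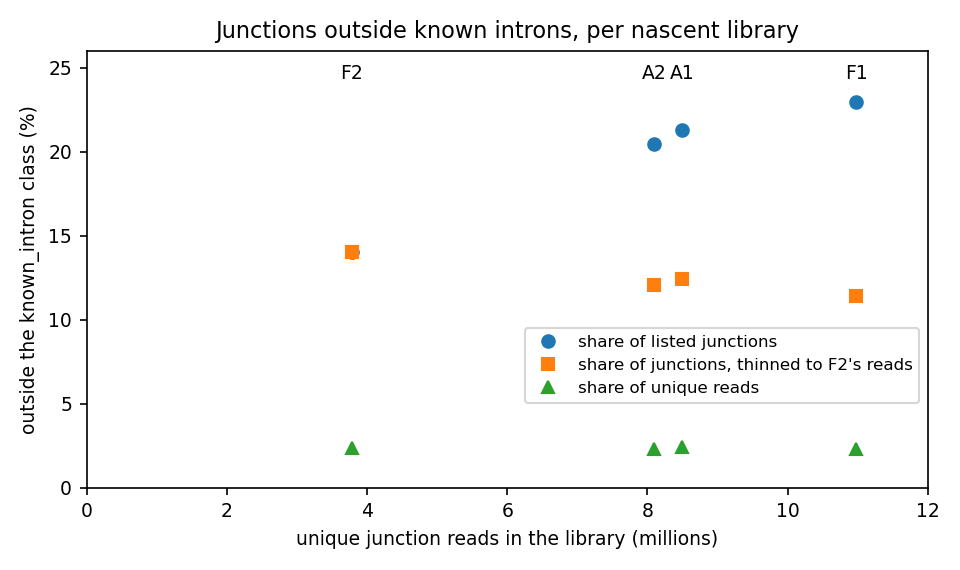
Share of junctions outside known introns (percent, vertical axis) against unique junction reads per library (horizontal axis, in megareads) for the 4 nascent libraries. Circles show listed junctions, squares show junctions after thinning to the reads of F2, where both symbols coincide at 14.01%, and triangles show the share of unique reads, between 2.31% and 2.41%.

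Most other-class junctions were seen in 1 library. Of known introns, 76.2% were listed in all 4 libraries and 8.74% in 1 only. Of junctions outside known introns, 8.52% (6502 of 76305) were listed in all 4 and 65.9% in 1. At the same total reads, known introns would have given 9.18%. Observed and matched shares differed by -0.656 percentage points. That gap is about as large as the -0.52 points found in simulated data with no difference. The share in all libraries was 20.7% for the small class called not_found, 12.3% for exonic junctions, 9.90% for 3′ matches and 8.64% for 5′ matches. It was 7.95% for junctions with no known end, 7.27% for multiple-match junctions and 6.11% for intronic ones. Known introns with the same total reads would have given 20.3%, 13.7%, 10.8%, 9.44%, 8.11%, 8.16% and 6.56%, in the order of these classes. The ranking of classes thus largely followed their reads. Without F2, 15.2% of the junctions outside known introns in the other 3 libraries were in all of them.

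Junctions that keep a 5′ splice site were shorter than known introns, and multiple-match junctions were longer. The per-library median span of known introns averaged 1522 bp ± 22.1 (SD, n = 4). It averaged 1210 bp ± 69.8 (SD, n = 4) for 5′ matches, 0.795 times that of known introns. It was 1684 bp ± 132 (SD, n = 4) for 3′ matches, 5818 bp ± 363 (SD, n = 4) for multiple-match, 698 bp ± 154 (SD, n = 4) for intronic and 227 bp ± 17.3 (SD, n = 4) for exonic junctions. Each of these classes lay on 1 side of known introns in all 4 libraries, with exact sign-flip p = 0.125, the smallest that 4 libraries can give. At 3 reads per junction 3′ matches were shorter than known introns in A1 (exact p = 0.375). Weighted by reads, intronic junctions were longer than known introns in F1 (exact p = 0.375). Junctions with no known end, at 1447 bp ± 181 (SD, n = 4), lay on both sides of known introns (exact p = 0.5). When each read rather than each junction was weighted, known introns had a median of 814 bp ± 38.7 (SD, n = 4) and 5′ matches were 1.35 times as long, which turns the direction. Junctions with no known end were then 1.43 times as long and longer in all 4 libraries (exact sign-flip p = 0.125).

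The free ends of partial matches lay mostly inside the known intron. Among 5′ matches whose known end was in use, 60.7% (11271 of 18567) ended within the shortest known intron from that site, and 36.6% beyond the longest. Among 3′ matches, 73.7% (11482 of 15587) began within the intron. Free ends were frequent close to the known site: 15.2% of 5′ matches ended within 12 bases of it, with 629 junctions 3 bases downstream and 529 junctions 4 bases downstream. Among 3′ matches 7.33% began within 12 bases, with 268 junctions 4 bases into the intron. Inside introns, the last decile of the length held 18.9% of the free ends of 5′ matches, and the first decile held 21.5% of those of 3′ matches. The flag for annotated junctions was set for 33.9% of 5′ matches and 38.4% of 3′ matches, against 98.99% of known introns. It was also set for 20.5% of junctions with no known end, so some of their ends are annotated.

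**Figure D2:**
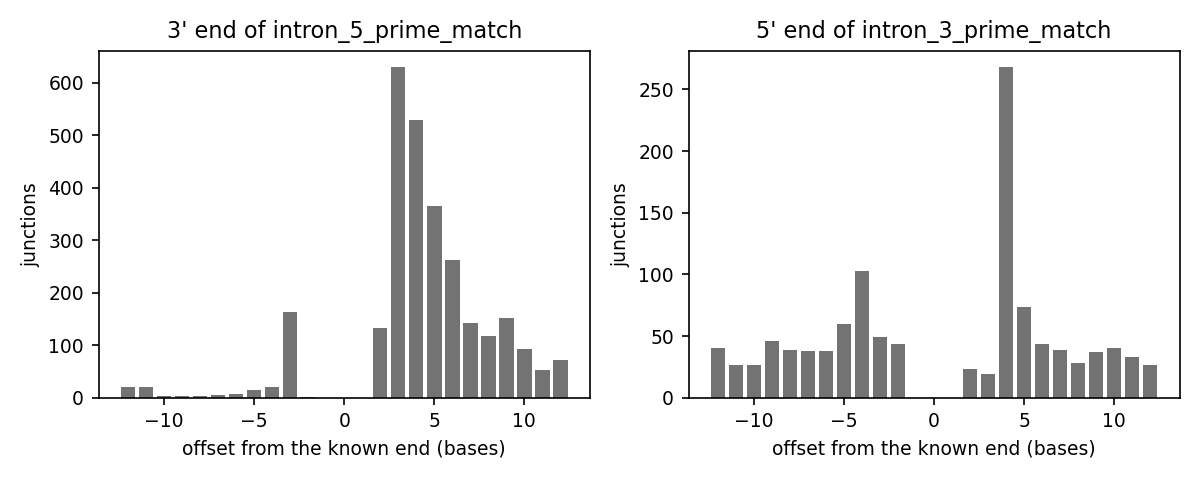
Number of junctions (vertical axis) by the offset in bases of the free end from the end of the shortest known intron that shares the other end, positive downstream, over the 4 nascent libraries together. Ends 3 and 4 bases downstream of a known 3′ splice site (629 and 529 junctions) and 4 bases downstream of a known 5′ splice site (268 junctions) are the highest bars for each kind of end.

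The ends of other-class junctions carried the usual intron motif to different degrees. Among junctions with at least 3 reads, GT/AG ends were found in 99.1% ± 0.0117 (SD, n = 4) of known introns, 99.5% ± 0.069 of 5′ matches, 99.6% ± 0.0698 of multiple-match junctions and 97.2% ± 0.233 of 3′ matches (SD, n = 4 for each). The share was 91.7% ± 2.45 for intronic junctions, 90.9% ± 2.49 for those with no known end, 85.7% ± 2.59 for exonic ones and 68.6% ± 1.08 for those called not_found (SD, n = 4 for each). Over all listed junctions, GC/AG ends made up 12.5% ± 1.54 of exonic ones, 10.1% ± 2.61 of those with no known end and 9.49% ± 3.05 of intronic ones (SD, n = 4 for each), against 0.798% ± 0.00925 (SD, n = 4) in known introns. Ends other than GT/AG, GC/AG and AT/AC made up 23.6% ± 1.44 (SD, n = 4) of junctions called not_found and were absent from the other classes compared here. The not_found junctions of this kind with the most reads had no strand in the lists. Whether the missing strand set their class was not tested. Of junctions with no known end, 73.3% fell in no cluster of known introns on either strand, and 22.0% lay only in a cluster on the opposite strand. Falling in no cluster does not mean lying away from known introns. It also held for 13.8% of 5′ matches, though 96.0% of that class shared a 5′ end with a known intron. Of intronic junctions, 91.8% lay in a cluster on their own strand.

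Other-class junctions with reads in every library were found more often in clusters with many reads, which such a minimum itself favours. At 3 or more reads in every library, 1686 of 18132 clusters (9.30%) carried at least 1, and 2616 such junctions were found in clusters. The decile of clusters with the most known-intron reads held 48.7% of them, and 37.4% of its clusters carried at least 1, against 0.0551% in the lowest decile. With every listed junction counted, at 2 or more reads in any library, it held 31.6% of 50722 junctions, and no comparison with the share expected from depth was made. The most, 12, lay in a cluster on chromosome 5 (180664043 to 180670691, minus strand) with 7 known-intron junctions and 33689 ± 12041 reads per library (SD, n = 4). A cluster on chromosome 3 (46712555 to 46735132, minus strand) carried 9. Multiple-match junctions at this level were found, for example, in a cluster on chromosome 12 (27127161 to 27167010, minus strand), with 5. Intronic ones included 7 in a cluster on chromosome 20 (62201019 to 62203460, minus strand), which held 391 ± 87.4 reads per library (SD, n = 4).

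Single junctions with many reads occurred in several classes. The known intron with the most reads lay on chromosome 1 (153536364 to 153537981, minus strand), with 22602 ± 8142 unique reads per library (SD, n = 4). The 5′ match with the most reads shared its 5′ end, 153537981, and ended 34 bases beyond it at 153536330, with 1002 ± 340 reads (SD, n = 4). The leading 3′ match (153534068 to 153535890, minus strand, GC/AG ends) lay in the same region, with 650 ± 235 reads (SD, n = 4). The leading intronic junction, on chromosome 1 (209603846 to 209605087, plus strand), had 442 ± 263 reads (SD, n = 4). The leading exonic junction, on chromosome 12 (125396727 to 125397866, minus strand), had 3644 ± 915 unique reads per library (SD, n = 4). It also had 3227 to 4635 multiply mapped reads per library, so its level is uncertain.

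A cluster of junctions on chromosome 2 was higher in the libraries with the letter F than in those with the letter A. Between 2 libraries of each letter, 61 of 96575 tested junctions differed (edgeR quasi-likelihood, adjusted p under 0.05), 51 higher and 10 lower in F. Of the 61, 42 lay in a single cluster on chromosome 2 (216226350 to 216300377, minus strand, 50 known-intron junctions), and all 42 were higher in F. As CPM of unique junction reads, this cluster had 3168 ± 463 in A and 11562 ± 857 in F (SD, n = 2 each), 3.65 times as many. Its junction at 216256538 to 216257653 rose by a log2 fold change of 2.85 ± 0.37 (SE, edgeR adjusted p = 0.0111), from 8.41 ± 4.43 CPM to 60.8 ± 4.97 CPM (SD, n = 2 each). Its junction at 216257927 to 216259250 rose by 2.68 ± 0.34 (SE, edgeR adjusted p = 0.00783), from 5.66 ± 1.43 CPM to 36.4 ± 2.86 CPM (SD, n = 2 each). Elsewhere 9 junctions were higher and 10 lower in F. A junction lower in F lay on chromosome 16 (30075827 to 30078554, plus strand), with a log2 fold change of -2.92 ± 0.42 (SE, edgeR adjusted p = 0.0206), from 15.8 ± 3.55 CPM to 2.23 ± 0.832 CPM (SD, n = 2 each).

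**Figure D3:**
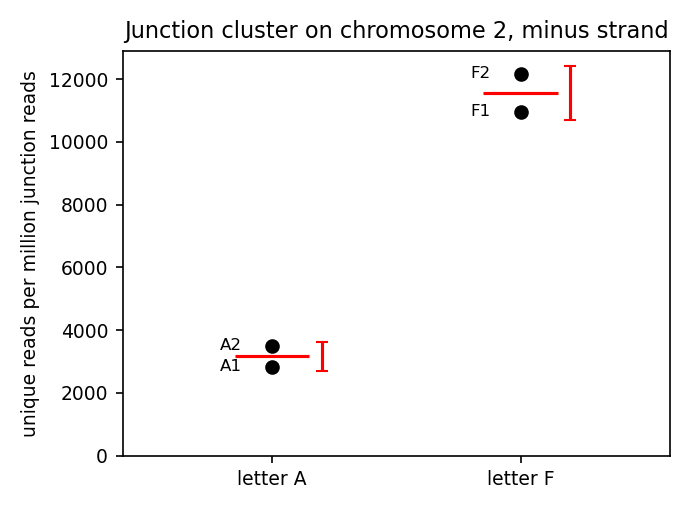
Unique reads of the junction cluster on chromosome 2 (216226350 to 216300377, minus strand) as CPM, per nascent library. Points are libraries, lines are means and bars are SD (n = 2 per letter), with means of 3168 for letter A and 11562 for letter F.

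By class, the differing junctions were 56 of 93426 tested known introns (0.0599%), 3 of 670 with no known end (0.448%) and 2 of 394 multiple-match junctions (0.508%), and the difference between these rates was not tested. The balance of other classes to known introns differed between letters in 0 of 4532 clusters tested (edgeR interaction, smallest adjusted p = 0.997), with 97 at an unadjusted p under 0.05. Without A2 it differed in 2 clusters and without F1 in 4. The share of junctions outside known introns was 20.9% in A and 18.5% in F, a difference of -2.36 percentage points (exact permutation p = 1, n = 2 each). At equal reads the difference was 0.461 points (exact permutation p = 1), and without F2 it was 2.12 points. The count of differing junctions rested on single libraries: it was 24 without A1 (13 higher and 11 lower in F), 265 without F1 (164 lower, and 38.1% higher) and 326 without F2 (201 higher and 125 lower), where the lone library of a letter is assumed to vary like the others. In simulated data, with changes placed only in junctions with many reads, 2% of 2-fold changes were called, so changes of that size were mostly not detectable in this design. Whether depth or the number of libraries set this limit was not tested.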

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

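The tests of library F2 at equal reads on GT/AG ends and on numbers of junctions were set before their results were seen, and the other explanation tested here was chosen after. Of 54 values compared over the 4 libraries, 4 set 1 library far from the other 3, and in all 4 it was F2. Chance flags about 1 in 20 such groups. In F2, intronic junctions made up 1.59% of listed junctions, against 2.09% to 2.17% elsewhere. Junctions with no known end made up 3.33%, against 4.31% to 4.42%. With the other libraries thinned to the reads of F2 both turned, and the others held 0.93% to 1.18% of intronic junctions and 2.06% to 2.49% of junctions with no known end. Multiply mapped reads made up 3.85% of junction reads in F2, against 4.15% to 4.17%. The GT/AG share of known introns was 99.12% there, against 99.10% in each of the others.

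F2 also had the fewest reads and the lowest share of junctions outside known introns. Its smaller number of reads may account for that low share. With the other libraries thinned to its total, F2 at 14.01% was no longer the lowest but the highest, against 11.4% to 12.4%, and over 20 further draws the other libraries reached at most 12.5%. Technical explanations of this excess were tested, and 78.7% of the excess remained among GT/AG junctions alone, which argues against junctions with other ends as its source. F2 listed 18589 junctions outside known introns, against at most 15789 in the thinned libraries. It also listed more known introns, 114108 against 111396 to 111777. Both argue against a smaller number of known introns as its source. After the drop of junctions under 2 reads, the thinned libraries held 3763055 to 3765767 reads, slightly below the 3785119 of F2. A library with less repeated sampling of the same molecules remains open, since the lists carry no molecular identifiers, and no biological explanation was tested.

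Multiply mapped reads, which were not counted in the levels compared, made up a larger share in the other classes than in known introns. They were 56.2% ± 4.602 (SD, n = 4) of reads on junctions with no known end and 58.9% ± 1.70 on exonic junctions, against 2.96% ± 0.0933 on known introns (SD, n = 4 for each). In other classes they were 28.7% for junctions called not_found, 21.7% for 3′ matches, 21.2% for intronic, 16.8% for multiple-match junctions and 10.7% for 5′ matches.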

How the results depend on the processing

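The alternatives were fixed before the data were examined, apart from clusters and multiply mapped reads, which were chosen after seeing the data. For junctions that differed between letters (61), RLE size factors, a minimum of 10 reads in every library, DESeq2, known introns alone and junctions in all 4 libraries gave 46 to 71. No filter gave 126, and leaving out 1 library gave 24 (without A1) to 326 (without F2), with 265 without F1, where the lone library of a letter is assumed to vary like the others. The cause was not tested. Sums over clusters gave 12 (7 higher and 5 lower in F), or 14 and 11 with a shorter and a longer link, where fewer units are tested. With the title number as a replicate block the count was 153 per junction (52 lower in F, and 66.0% higher) and 105 per cluster (65 higher and 40 lower), and all 61 junctions called without the block were called with it, in the same direction. Of the 153, 49 lay in the cluster on chromosome 2 and 104 elsewhere, and 14 junctions lower in F met the naming rule, against 1 without the block. The split by number, 251 on its own, gave 975 with the letter held, 879 lower in number 2. Whether libraries of 1 number were handled together is not stated. With 2 pairs, number 1 minus number 2 in A correlated with the same in F at 0.235 across 53642 junctions. The letter gave less: F minus A at number 1 correlated with the same at number 2 at 0.0871. The interaction count of 0 became 4 with no filter and 0 to 4 without 1 library, 2 without A2 and 4 without F1, and the cause was not tested. It stayed 0 with the block and with other links.

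The share of junctions outside known introns (19.7%) was 12.7% at 3 reads, 3.23% at 10 reads, 2.35% of unique reads, 3.48% of unique and multiply mapped reads, 12.5% after thinning, and 18.6% to 21.6% without 1 library. Its letter difference (-2.36 points) turned to 0.461 after thinning and to 2.12 without F2, with a range of -6.85 to 2.12 without 1 library. The share in all libraries (8.52%) was 34.1% for at least 2 libraries, 10.4% at 3 reads, 8.93% after thinning and 11.9% to 15.2% (without F2) over 3 libraries, where fewer libraries are required. The span ratio of 5′ matches (0.795) was 0.731 at 3 reads, 1.35 weighted by reads, and 0.779 to 0.807 without 1 library. That of junctions with no known end (0.9497) turned to 1.43 weighted by reads and ranged from 0.915 to 1.0006 (without F2) without 1 library. The cause was not tested. GT/AG ends outside known introns (95.4%) were 94.0% at 10 reads. Clusters with other classes (9.30%) rose to 58.7% with every listed junction counted, at 2 or more reads in any library. Of 167 further values of single classes, 68 moved by less than their spread, 97 by more and 2 turned direction.

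The planned match on known-intron reads and longest span was for random lists set against gene lists, and was not run, like the other alternatives of the gene lists, since the lists hold gene names. The second workbook held identical values. Depth limits junctions with few reads, which the lists drop below 2.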

Other observations

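The tests reported here were chosen after the result was seen, except those of whole-codon segments and of equal spans, which were set before. The title number split the libraries more than the letter did. Between libraries numbered 1 and 2, 251 junctions differed (edgeR quasi-likelihood, adjusted p under 0.05, 2 against 2), 249 of them lower in number 2. Between letters 61 differed. The remaining way to part the libraries 2 against 2 gave 0 by edgeR, with 2398 junctions at an unadjusted p under 0.05. The junctions that differed by number lay in 72 clusters, most often, with 17, in a cluster on chromosome 3 (48601856 to 48632507, minus strand). That cluster had 9384 and 10035 CPM of unique junction reads in A1 and F1, and 3707 and 5325 in A2 and F2. What the number stands for is not stated, and number 2 was the shallower library of each letter.

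Pairs of a 5′ match and a 3′ match inside 1 known intron were often separated by the length of a short exon. Within 500 bases, 4906 such pairs were found, and 3181 had a gap of at least 50 and under 200 bases, with both junctions flagged annotated in 1241 and neither in 1429. The median of positive gaps was 113 bases.

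Gaps of at least 50 and under 200 bases held 12.8 times as many pairs per base as overlaps of more than 100 and up to 500 bases, which argues against unrelated partial matches falling near each other. Internal exons missing from the annotation behind the classes are a candidate explanation. Whole-codon lengths made up 34.4% of the 1429 unflagged segments (exact binomial interval 31.97% to 37.0%), and chance gives 33.3%. The 1241 flagged segments had 34.9%, so the test could not decide whether the others were coding exons, which remains open.

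Adjoining pieces taken separately out of 1 intron would give junctions that meet at 1 site with no base between them. Removal in pieces need not leave such pairs, so their number does not measure how often it occurs. Inside single known introns, 5 such pairs were found, on chromosomes 1 (site 44679334), 10 (135105482), 20 (61484075), 6 (35436373) and 8 (22053710), with at most 7 reads per junction and library. In the pairs on chromosomes 10, 20 and 8, at least 1 junction was listed in 1 library only, with 2 reads. Both junctions were flagged annotated in the pair on chromosome 1 and neither in the other 4. These places were chosen after their values were seen. Over all classes outside known introns, 340 pairs met end to end, with a 5′ match, an intronic junction or one with no known end first. Pairs whose spans had a common divisor of at least 12 bases had 71.8% multiply mapped reads, and the 175 pairs without one had 28.8%. Of those 175, 36 had both junctions in at least 2 libraries.

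The 5 pairs compare with 8 over the 20 neighbouring gaps and overlaps of 1 to 10 bases (Poisson probability 6.12e-05), and the 340 with at most 25 at any other gap or overlap up to 10 bases, which argues against chance adjacency and against splice sites drawn at random near each other. Tandem repeats remain a possible explanation for part of the 340. Equal spans, the mark of repeats that give junctions of 1 length, were found in 12.9% of pairs, and spans with a common divisor of at least 12 bases in 48.5%, against at most 17.9% in 1000 shuffles. The 27 pairs led by a 5′ match had 0 equal spans and 8.72% multiply mapped reads. Of these 27, 26 had no common divisor of at least 12 bases. A 5′ match begins at a known splice site, so its span need not be a multiple of a repeat unit. The tests on spans therefore cannot decide on repeats for those pairs, and recursive splicing was not shown. Both junctions were flagged annotated in 7 of the 27, and both were in at least 2 libraries in 7. Equal spans lay in the 169 pairs led by an intronic junction (25) and the 144 led by one with no known end (19). For these, recursive splicing and repeats cannot be told apart. Over all 340 neither test on spans decided, and the genome sequence of the build was not used here.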
